A study of Bos taurus with 7 samples.

How the data were processed

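Total RNA of the rumen epithelium of 7 Holstein calves was measured on 7 single-colour Agilent arrays, 1 array per calf. Per the labels, 3 calves were given forage (HAY, calves 9, 10 and 13) and 4 were not (CON, calves 8, 11, 12 and 14). Cyanine 3 labelled RNA was made from 500 ng of total RNA with a linear amplification kit, per the labels' protocols. Each calf is a separate animal and counts as 1 replicate. Groups and calf numbers were taken from the labels, and the calf numbers do not pair animals across groups.

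The deposited scanner output holds the spot intensity on a linear scale, with background subtraction and detrending within the array by Agilent Feature Extraction 9.5, per the file headers and the submitters' processing notes. These values had not been scaled between arrays. The deposited whole-series table holds log2 values of the same signals. Set against the scanner values, each of its columns equalled the log2 mean signal of a probe minus the 75th percentile of its array, with a Pearson correlation of at least 0.9999998 and an SD of the difference of at most 0.00224. Its scale, direction and lack of centring per gene were therefore settled from the data. Its column medians were -3.14, -3.16 and -3.23 in HAY calves 9, 10 and 13. They were -3.11, -3.11, -3.11 and -3.13 in CON calves 8, 11, 12 and 14.

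Each array carried 15110 spots of 15008 probes besides 536 control spots, and 24 probes were printed as 6 spots each. The probes are 60 bases long. Control spots and spots marked as outliers by the scanner software were left out, and saturated spots were kept. The spots of a probe were averaged on the log2 scale, and the 75th percentile of the probe values of each array was then subtracted. A log2 value of 0 therefore equals the 75th percentile of the array's own signals. Between 81.5 and 84.6% of the spots per array were well above background, between 10 and 20 spots were saturated, and the median coefficient of variation among repeated spots was 8.18 to 10.9%. The number of arrays limits the precision.

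Gene names came from the RefSeq accession of the probe, matched without version to a gene table of assembly ARS-UCD2.0 that was used for names only. This named 11682 probes and updated 755 symbols. The other 3326 probes kept the name in the file, 322 of them without a gene symbol. The array holds 14961 distinct gene names, of which 34 have more than 1 probe. For these the probe with the highest mean signal was used, and the mean of the kept probes was an alternative. Coordinates are those the deposited files give, on UMD_3.1. They say where a probe lies, and exon and UTR annotation of that build was not used here.

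Probes well above background on at least 3 of the 7 arrays were kept, which left 12604 probes and 12570 genes. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A further count took genes at least 2-fold different at an unadjusted p under 0.05. For 27 lists of genes fixed before the data were examined, camera was run with a preset correlation of 0.01, with an estimated correlation, and beside fry, each with Benjamini-Hochberg adjustment over the lists. List members were matched on the updated symbol or on the name in the file, and 10 matched only on the latter, some of which now carry a locus name. A list score is the mean over members of the log2 deviation from the mean of the 7 arrays, compared between groups by an exact two-sided permutation test over all 35 splits of 3 against 4. The smallest p this test can give is 0.0286.

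A probe not well above background on any array of a group has only a bound there. The fold is then given as at least the mean of the brighter group over the mean, in the other group, of the higher of the probe's own value and the lowest signal among probes well above background on that array. Such a bound concerns the group means with the main processing and carries no sampling error. Another background correction can give a smaller difference.

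The named genes followed a rule set before the data were examined. It took up to 12 genes per direction with the largest differences among those past the threshold and without overlap between groups. Places left over were filled by the smallest unadjusted p under 0.05 without overlap, leaving out names that are only a locus or clone number. It added up to 4 members of smallest p from each list that passed or had a member past the threshold adjusted over the list alone, and 10 genes of prior interest. Of the latter, MKI67 was not measured here. Some genes that the rule selected are not reported here and were not replaced, which left 80 tested genes.

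All 7 arrays lay on 1 slide and were read in 1 scan, so neither could serve as a block. The HAY arrays occupied row 1 of the slide, in columns 2, 3 and 4, and the CON arrays row 2, in columns 1 to 4. Slide row and feeding group cannot be told apart, while the slide column could be fitted as a block. Column 1 held only CON calf 8, so the block leaves this calf out of the comparison. The alternatives tried were normexp background correction with offset 50, quantile normalization, median centring, the deposited log2 table, no filter on dim probes, a filter on all 7 arrays, the mean of probes per gene, the trend and robust options of eBayes, the slide column as a block, and leaving out each calf in turn. A covariate for stromal content, an estimated correlation with it or with the slide column, leaving out calves 8 and 13 together, and leaving out each calf from the comparison of array correlations were added after the data were seen.

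The fit was tested on simulated data with the real means and SDs of 12561 genes, in 10 rounds with 200 genes changed per round. For this comparison it called 45.6% of the genes changed 2-fold, 83.2% of those changed 4-fold, 92.4% of those changed 8-fold and 96.8% of those changed 16-fold, and 4.9% of its calls were false. Simulated genes vary independently of each other, unlike those of the calves. With 200 changed genes the adjustment is also less strict than where few genes change. The rates therefore hold for this setting and are not the power of the comparison of the calves. With 1 list shifted by 1 log2 unit, camera called it in 20 of 20 rounds and called 1 of 520 tests of other lists. Figures were drawn with matplotlib 3.10.9.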

Results

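Gene expression was measured in the rumen epithelium, the keratinised lining of the forestomach that takes up the short-chain fatty acids of fermentation, of 7 Holstein calves. The series concerns dietary forage and calf starter, rumen pH and the adaptation of the epithelium around weaning. The calves had been divided into a group given forage (HAY, n = 3) and a group without forage (CON, n = 4), with 3 weeks after weaning named in the design. The question was which genes differ between the epithelia of the 2 feeding groups. The median processed signal was 217, 215 and 241 intensity units in HAY calves 9, 10 and 13, and 222, 224, 182 and 229 in CON calves 8, 11, 12 and 14.

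B4GALNT2, which encodes a glycosyltransferase that adds N-acetylgalactosamine to cell surface glycans, was lower in HAY than in CON. Its log2 signal was -6.33 ± 0.22 (SD, n = 3) in HAY and -1.52 ± 0.38 (SD, n = 4) in CON, a 28.1-fold lower level in HAY (log2 difference -4.81, SE 0.23, limma adjusted p = 0.000814). With normexp background correction, whose offset shrinks differences of dim probes, the log2 difference was -3.12. All 3 HAY calves lay between -6.56 and -6.12, and all 4 CON calves between -1.86 and -0.98. The probe lies on chromosome 19 from 38026700 to 38026759 of UMD_3.1. B4GALNT2 was the only 1 of 12570 tested genes past the threshold with limma, beside 1753 genes at an unadjusted p under 0.05. Chance gives 628.5 on average, but other splits of the same 7 calves reached more than 1753. They gave 2512 with calves 10, 13 and 14 set apart and 1870 with calves 8, 11 and 12 set apart. Of the 1753 genes, 852 were higher and 901 lower in HAY, a balance that moved with the processing: 1237 were higher and 774 lower with median centring, 1052 and 841 with quantile normalization, and 664 and 1145 with the slide column as a block. At an unadjusted p under 0.05 and a difference of at least 2-fold stood 590 genes, 125 higher and 465 lower in HAY, none of which except B4GALNT2 passed the adjustment. The groups did not overlap in 1487 genes (11.8%), where chance gives 5.71% on average over splits. Genes that vary together widen the spread around this average, so the excess alone is no evidence of a group effect.

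The count past the threshold was 21 without CON calf 14, 7 without HAY calf 9, 4 without CON calf 8 and 2 without HAY calf 13, and the 2-fold count was 950 without HAY calf 9 and 342 without HAY calf 13. At an unadjusted limma p under 0.05 stood 2342 genes without HAY calf 9, 987 without HAY calf 10 and 982 without HAY calf 13. Slide row and feeding group cannot be told apart, since the HAY arrays lay in row 1 and the CON arrays in row 2.

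**Figure D1:**
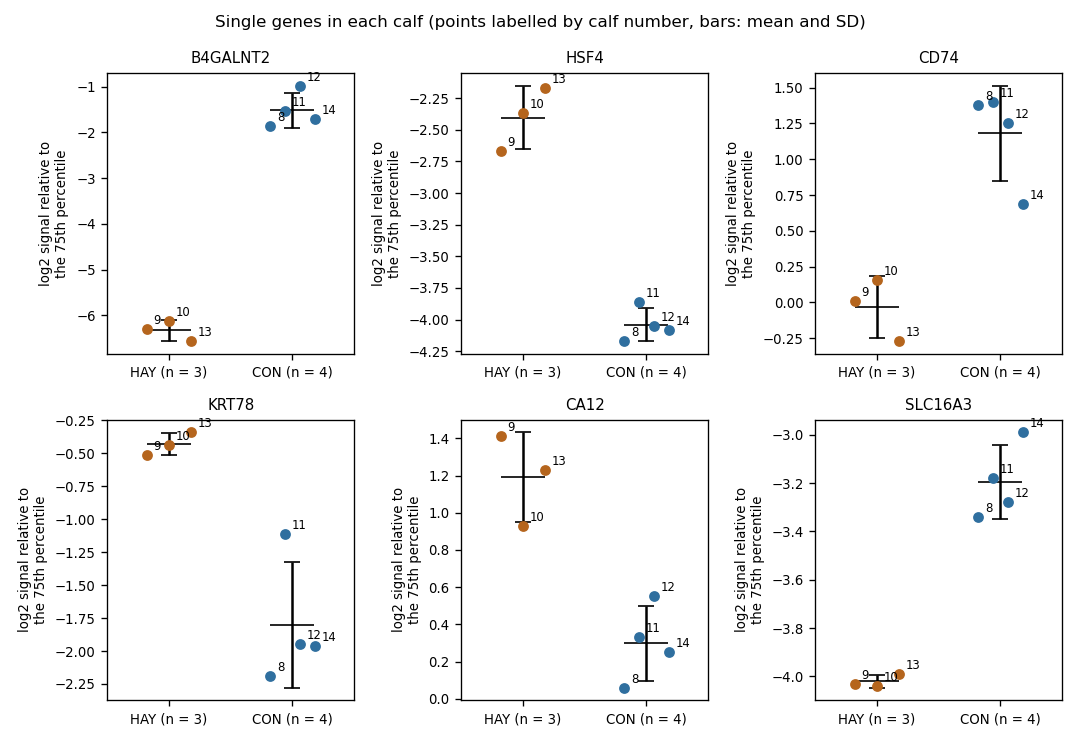
Log2 signal relative to the 75th percentile of each array (vertical axis) of 6 genes in the 3 HAY and 4 CON calves. Points are calves, labelled by calf number, and bars give the mean and SD. B4GALNT2 lies between -6.56 and -6.12 in HAY and between -1.86 and -0.98 in CON, and none of the other 5 genes passed the adjustment over all genes.

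Among genes with higher values in HAY, none passed the adjustment with limma over all genes, and those named here had the smallest unadjusted p without overlap between groups. HSF4, a heat shock transcription factor, was 3.11-fold higher in HAY (log2 difference 1.64, SE 0.16, adjusted p = 0.0582). CFAP70, a protein of cilia and flagella, was 2.25-fold higher (log2 difference 1.17, SE 0.13, adjusted p = 0.0584). The membrane protein gene TMEM61 differed by 1.61 log2 units, the synaptic vesicle gene SYNPR by 2.78, the alpha tubulin gene TUBA1D by 2.47 and the ephrin receptor gene EPHB6 by 1.02. DMRT2, a transcription factor, differed by 3.21 (SE 0.52), ENTPD5, a nucleotidase of the endoplasmic reticulum, by 1.58 (SE 0.27), and the mitochondrial ribosomal gene MRPL14 by 0.84. The sialyltransferase gene ST8SIA5 differed by 0.94 and, like SYNPR, was well above background on only 2 of the 4 CON arrays. ONECUT2 and WDR93 were not well above background on any CON array. With the main processing the bound on the group means was at least 1.24-fold higher in HAY for each (adjusted p = 0.164 for both), which did not hold with normexp. With normexp the log2 difference was -0.088 for ONECUT2, 0.039 for WDR93, 0.097 for ST8SIA5, 0.64 for SYNPR, 1.68 for DMRT2 and 0.32 for MRPL14.

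Genes with lower values in HAY were chosen in the same way, and none besides B4GALNT2 passed the adjustment. CORO1A, an actin-binding protein of leukocytes, was 2.81-fold lower in HAY (log2 difference -1.49, SE 0.18, adjusted p = 0.0963). CD1E, a lipid antigen presentation protein of dendritic cells, had a log2 difference of -1.88 (SE 0.25) and DSB, an MHC class II gene of cattle, of -1.45 (SE 0.18). MOCOS, the molybdenum cofactor sulfurase, had a difference of -1.26, the scavenger receptor gene SCARA3 of -1.17, the small GTPase gene RAB38 of -2.20 and SOSTDC1, a secreted inhibitor of BMP and Wnt signalling, of -1.04. CHI3L1, a secreted glycoprotein of inflamed tissue, and DIRAS3, a small GTPase, had differences of -3.44 and -2.42 and were well above background on 1 of the 3 HAY arrays each. With normexp the difference was -0.96 for CHI3L1, -0.60 for DIRAS3, -1.15 for RAB38, -1.18 for CD1E and -0.58 for MOCOS.

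Of the 27 gene lists, 8 passed camera with its preset correlation, 6 of them lower and 2 higher in HAY. With an estimated correlation none passed (lowest adjusted p = 0.515), 2 lists having an unadjusted p under 0.05, and none passed fry's directional test (4 at an unadjusted p under 0.05). No list passed the exact permutation test of its score over calves either (lowest adjusted p = 0.257). Fry's test for change in either direction, which does not compare a list with other genes, passed 8 lists, with the smallest adjusted p, 5.15e-05, for the transport of acids and short-chain fatty acids. With the slide column as a block, which also takes CON calf 8, alone in its column, out of the comparison, 12 lists passed camera with its preset correlation, the same 8 and 4 more: toll-like receptors and inflammation (lower in HAY, adjusted p = 0.0058), the cell cycle (higher, adjusted p = 0.0304), the cornified layer (lower, adjusted p = 0.0355) and T and NK cells (lower, adjusted p = 0.0365). Without CON calf 8 and with no block, toll-like receptors and inflammation (adjusted p = 0.00239) and the cornified layer (adjusted p = 0.0209) passed, and the other 2 did not. With an estimated correlation, chosen after the data were seen, none passed in the blocked fit (adjusted p = 0.834, 0.834, 0.834 and 0.798 for these 4).

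Smooth muscle, fibroblast and endothelial genes were lower in HAY. All 17 fibroblast and matrix genes had lower values in HAY, with a median log2 difference of -1.47 (camera adjusted p = 3.83e-07, and adjusted p = 0.515 with an estimated correlation). POSTN, a matrix protein, had a difference of -1.78 (SE 0.54), the collagen gene COL6A1 of -1.64 (SE 0.54), SPARC of -1.47 (SE 0.47) and FBLN1 of -1.15 (SE 0.36). All 14 smooth muscle genes were lower too, with a median of -1.25 (camera adjusted p = 9.01e-07, and adjusted p = 0.515 with an estimated correlation). ACTA2, smooth muscle actin, at -1.33 (SE 0.28) and DES, desmin, at -3.25 (SE 0.84) passed when adjusted over the list alone, and DES was well above background on 2 of 3 HAY arrays. TAGLN and MYLK, at -1.42 and -1.21, did not pass. Of 16 endothelial genes 14 were lower, with a median of -0.73 (camera adjusted p = 7.58e-05, and adjusted p = 0.515 with an estimated correlation). ENG had a difference of -0.73 (SE 0.21), PECAM1 of -1.05 (SE 0.39), TIE1 of -0.72 and PLVAP of -0.80. No fibroblast or endothelial gene passed when adjusted over the list alone, and no gene of these 3 lists passed over all genes. With normexp DES had a difference of -1.57, and without HAY calf 13 PECAM1 had one of -0.60, TIE1 of -0.41 and PLVAP of -0.37.

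The stromal score, the mean of the smooth muscle and fibroblast scores, was -0.70 ± 0.71 (SD) in the 3 HAY calves and 0.53 ± 0.73 (SD) in the 4 CON calves (exact permutation p = 0.114, two-sided). The groups overlapped: HAY calf 9 stood at 0.08 and CON calf 14 at -0.16. With this score as a covariate, chosen after the data were seen, the fibroblast median was 0.15 and the endothelial median 0.07, and neither list nor smooth muscle, at -0.05, passed. ACTA2 then had a difference of -0.75, DES of -1.10, TAGLN of -0.33, MYLK of -0.07, POSTN of -0.40, COL6A1 of -0.32, SPARC of -0.24, FBLN1 of -0.23, PECAM1 of -0.34, TIE1 of -0.17 and PLVAP of -0.41. For the smooth muscle and fibroblast genes this shrinkage was set in advance, since the score is made of their own values, and it tells nothing of the cause. Only the endothelial genes lie outside the score. Without HAY calf 13 the endothelial median was -0.37. Without calves 8 and 13, which had the highest and the lowest stromal score, it was -0.21 and the list did not pass (adjusted p = 0.0505), while fibroblasts, at a median of -0.73 (adjusted p = 0.000439), and smooth muscle, at -0.57 (adjusted p = 8.3e-05), did, all with the preset correlation. The 2-fold count was then 337, against 310 without calves 8 and 13.

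**Figure D2:**
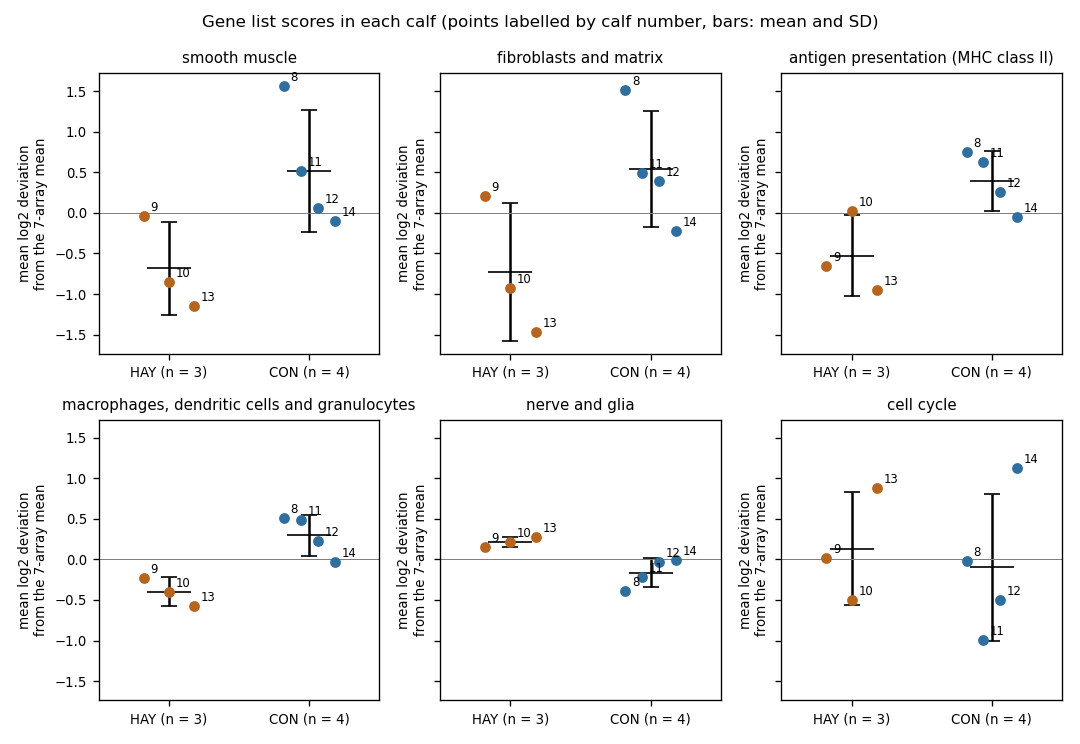
Scores of 6 gene lists (vertical axis: mean log2 deviation of the members from the mean of the 7 arrays) in the 3 HAY and 4 CON calves. Points are calves, labelled by calf number, and bars give the mean and SD. The groups overlap for fibroblasts and matrix, where HAY calf 9 stands at 0.21 and CON calf 14 at -0.22, and do not overlap for macrophages or for nerve and glia. The exact permutation p of the score is 0.0571 for macrophages and 0.0286 for nerve and glia, and neither passes the adjustment over the lists (adjusted p = 0.257 for both).

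Genes of antigen presentation and of myeloid cells were lower in HAY. All 12 tested genes of the MHC class II antigen presentation list had lower values, with a median log2 difference of -1.16 (camera adjusted p = 7.14e-06, and adjusted p = 0.515 with an estimated correlation), and 7 of them passed when adjusted over the list alone. The scores of the groups overlapped, with HAY calf 10 at 0.02 and CON calf 14 at -0.06 (exact permutation p = 0.0857, adjusted p = 0.257). CD74, the invariant chain, was 2.32-fold lower in HAY (log2 difference -1.22, SE 0.21), BOLA-DRA 2.41-fold lower (-1.27, SE 0.29), BOLA-DRB3 2.89-fold lower (-1.53, SE 0.41) and CTSS, the cathepsin that trims the invariant chain, 2.29-fold lower (-1.20, SE 0.38). MHC class II genes vary between animals in sequence, which a short probe can read as a difference in level. Of 16 genes of macrophages, dendritic cells and granulocytes 14 were lower, with a median of -0.67 (camera adjusted p = 1.05e-05, and adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 5 passed, among them FCER1G at -0.76 (SE 0.18), CSF1R, the receptor of the macrophage growth factor, at -1.28 (SE 0.32), AIF1 at -0.91 (SE 0.23) and FCGR3A at -1.59 (SE 0.49). None of the genes of either list passed over all genes. With the stromal score as a covariate the median was -0.49 for MHC class II and -0.55 for the myeloid list. The difference was then -0.73 for BOLA-DRA, -0.76 for BOLA-DRB3, -0.38 for CTSS, -0.63 for CSF1R and -0.48 for FCGR3A, the last of which was -0.86 with normexp. Both passed camera with the preset correlation (adjusted p = 0.0025 and adjusted p = 0.0206) and neither with an estimated correlation (adjusted p = 0.536 for both). The myeloid score followed the stromal score across the 7 calves (Pearson r = 0.914, exact permutation p = 0.00258, adjusted p = 0.00387, and Spearman rho = 0.964, exact permutation p = 0.00278, adjusted p = 0.00556, over 6 relations computed), with r = 0.862 after centring within groups and r = 0.859 without calves 8 and 13. The MHC class II score had a Pearson r of 0.774 with it (exact permutation p = 0.0403, adjusted p = 0.0403) and a Spearman rho of 0.857 (exact permutation p = 0.0238, adjusted p = 0.0238), which rests on calves 8 and 13, since r was 0.321 without them, and r was 0.498 after centring within groups. The 6 relations were not planned, and the adjustment covers only them and no other pairs of lists, so their p-values may be too small.

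Interferon-stimulated genes were lower in HAY for 21 of 27 members, with a median of -0.23 (camera adjusted p = 0.00059, and adjusted p = 0.515 with an estimated correlation). The median was -0.43 without CON calf 14 and -0.14 without calves 8 and 13. The 3 members that passed when adjusted over the list alone were CXCL11, MX1 and OAS1Z. CXCL11, a chemokine that attracts T cells, was not well above background on any HAY array and at least 1.81-fold lower there. MX1, an antiviral GTPase, had a difference of -1.85 (SE 0.46) and OAS1Z of -1.39 (SE 0.35), the latter well above background on 1 of 3 HAY arrays. ISG20 had a difference of -1.26 and did not pass. With the stromal score as a covariate the list did not pass camera (median -0.21, adjusted p = 0.0501), and the difference was -0.85 for MX1, -0.84 for OAS1Z and -2.19 for ISG20. With normexp it was -0.46 for CXCL11 and -0.36 for OAS1Z. Its score had a Pearson r of 0.824 with the stromal score (exact permutation p = 0.0228, adjusted p = 0.0274) and a Spearman rho of 0.857 (exact permutation p = 0.0238, adjusted p = 0.0238). This rests in part on calves 8 and 13, since r was 0.502 without them, and r was 0.601 after centring within groups. The T and NK cell list had a median of -0.22 over 16 genes (camera adjusted p = 0.058). It passed with normexp (median -0.18, adjusted p = 0.0353) and without CON calf 14 (median -0.32, adjusted p = 0.00513), and not with an estimated correlation (adjusted p = 0.515). Of the 10 B and plasma cell genes 8 were higher in HAY (median 0.23, camera adjusted p = 0.252, and medians from 0.14 to 0.35 when each calf was left out). With the stromal covariate the medians of these 2 lists were -0.02 and 0.05.

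The tight and adherens junction list was higher in HAY, with 15 of 21 members above CON and a median of 0.21 (camera adjusted p = 0.0429, and adjusted p = 0.515 with an estimated correlation). TJP3 had a difference of 0.64 (SE 0.22) and PARD6B of 0.57 (SE 0.21), while MARVELD3 at 2.22 was well above background on only 1 of 4 CON arrays. No member passed over the list or over all genes, and CLDN1 differed by 0.21 (SE 0.20), or by 0.13 to 0.38 when each calf was left out. With normexp MARVELD3 differed by 0.23 and PARD6B by 0.37, and with the stromal covariate MARVELD3 by 3.82. All 8 nerve and glia genes were higher in HAY (median 0.33, camera adjusted p = 0.0445, and adjusted p = 0.515 with an estimated correlation). S100B differed by 0.65 (SE 0.24), STMN2 by 0.72 and GFRA3 by 0.21, and none passed. With normexp STMN2 differed by 0.12 and GFRA3 by 0.07, and with the stromal covariate S100B differed by 0.14, STMN2 by 1.60 and GFRA3 by 0.10. Without HAY calf 9 STMN2 differed by 0.32. The call of the nerve and glia list was lost with normexp (median 0.11, adjusted p = 0.258), with no filter on dim probes (15 genes, median 0.19, adjusted p = 0.771) and with the stromal covariate (median 0.12, adjusted p = 0.406), and held in 6 of 19 alternatives. The call of the junction list was lost with quantile normalization (median 0.13, adjusted p = 0.153), without CON calf 14 (adjusted p = 0.264), HAY calf 9 (adjusted p = 0.0626) or HAY calf 10 (adjusted p = 0.0551) and with the stromal covariate (median 0.19, adjusted p = 0.0612), and held in 10 of 19.

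The cornified layer list went both ways, with 18 of 40 members higher and 22 lower in HAY (median -0.07, camera adjusted p = 0.252), and 5 passed when adjusted over the list alone. The list passed without HAY calf 13 (median -0.14, adjusted p = 0.0427) or CON calf 8 (median -0.12, adjusted p = 0.0209), and not with an estimated correlation in the main fit (adjusted p = 0.794). KRT78, a keratin of differentiated stratified epithelium, was 2.59-fold higher in HAY (log2 difference 1.37, SE 0.26). The serine protease genes KLK7 and KLK10 and the keratin gene KRT4 were lower. KLK7 and KRT4 were not well above background on any HAY array, and were at least 6.97-fold and at least 3.63-fold lower there. KLK10 had a difference of -3.40 (SE 0.81). With normexp the difference was -1.16 for KLK7 and -0.68 for KRT4. Fry's test for change in either direction, which 8 lists passed, gave it an adjusted p of 0.000127. Of 15 basal keratinocyte genes 10 were lower (median -0.15, camera adjusted p = 0.252, and medians from -0.29 without HAY calf 10 to 0.011 without HAY calf 13), and KRT5 differed by -0.10 (SE 0.17). Desmosomes and hemidesmosomes had 13 of 20 members higher (median 0.15, camera adjusted p = 0.404, and medians from 0.020 without HAY calf 10 to 0.23 without CON calf 11).

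Transport of acids and short-chain fatty acids also went both ways, with 19 of 29 members higher and 10 lower in HAY (median 0.05, camera adjusted p = 0.794, and medians from 0.050 to 0.17 when each calf was left out). The mean over members was negative, so that mean and median differ in sign. Adjusted over the list alone, 4 passed, CA12 with higher values in HAY and SLC16A3, CA13 and ATP1B1 with lower ones. CA12, a membrane carbonic anhydrase, was 1.86-fold higher (log2 difference 0.90, SE 0.18). SLC16A3, a monocarboxylate transporter, was 1.76-fold lower in HAY (-0.82, SE 0.13), CA13, a cytosolic carbonic anhydrase, 2.17-fold lower (-1.12, SE 0.21) and the sodium pump subunit gene ATP1B1 1.85-fold lower (-0.89, SE 0.22). The anion exchanger gene SLC26A3 differed by 1.05 (SE 0.38), the monocarboxylate transporter gene SLC16A1 by 0.40 (SE 0.23) and the sodium-proton exchanger gene SLC9A3 by 0.25 (SE 0.20), none of which passed. SLC9A3 differed by 0.013 with normexp and by 0.13 to 0.39 when each calf was left out. Transport of urea, ammonia, water and sugar had 12 of 17 members higher (median 0.11, camera adjusted p = 0.404, and medians from 0.035 to 0.28 when each calf was left out).

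Ketogenesis and butyrate use had 11 of 17 members higher in HAY and none past the threshold over the list or over all genes (median 0.17, camera adjusted p = 0.265). The median was 0.08 without HAY calf 9 or CON calf 8 and 0.27 without CON calf 12. BDH1, which makes the ketone body 3-hydroxybutyrate, was 1.53-fold higher (log2 difference 0.61, SE 0.22, limma adjusted p = 0.305).

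Antimicrobial and acute-phase genes had 11 of 23 members higher and 12 lower (median -0.40, camera adjusted p = 0.3), and 3 passed when adjusted over the list alone. The median was -0.08 without CON calf 8. HP, haptoglobin, was not well above background on any HAY array and at least 4.96-fold lower there, LYZ, lysozyme, had a difference of -1.44 (SE 0.34), and DUOX2, an oxidase of epithelial surfaces, was higher by 1.05 (SE 0.24). With normexp HP had a difference of -1.05, and with the stromal covariate LYZ had one of -0.66. LYZ belongs to a family of similar copies in cattle, which a probe may not tell apart. The beta-defensin gene EBD had a difference of -1.52 (SE 0.47) and did not pass. Toll-like receptors and inflammation had 18 of 37 members higher (median -0.06, camera adjusted p = 0.191). The list passed without CON calf 8 (median -0.19, adjusted p = 0.00239) and with no filter on dim probes (median -0.22, adjusted p = 0.0445), and not with an estimated correlation in the main fit (adjusted p = 0.794). TLR4 had a difference of -0.69 (SE 0.22, limma adjusted p = 0.273).

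In the growth factor list 10 of 15 members were higher in HAY (median 0.14, camera adjusted p = 0.925, and medians from 0.062 to 0.22 when each calf was left out), and its mean was negative. HBEGF, an epidermal growth factor receptor ligand, at 0.81 (SE 0.20) and IGFBP2 at -1.49 (SE 0.40) passed when adjusted over the list alone, while IGFBP7 at -1.88 (SE 0.60), IGF1 at -1.47 (SE 0.56) and IGFBP5 at 0.04 (SE 0.33) did not. With the stromal covariate HBEGF differed by 0.45, and IGFBP7 had a difference of -0.62 and IGF1 of -0.019. With normexp IGFBP2 had one of -0.68 and IGF1 of -0.79, and without HAY calf 13 IGFBP7 had one of -1.17. Among 20 immediate early genes 12 were higher (median 0.08), with camera's direction and the mean negative (camera adjusted p = 0.404, and medians from -0.018 to 0.12 when each calf was left out). CCN2, a matricellular protein, at -2.52 (SE 0.44) passed when adjusted over the list alone, and DUSP1 at -0.69, ATF3 at -1.28 and JUND at -0.58 did not. With normexp CCN2 had a difference of -1.13, with the stromal covariate DUSP1 had one of -0.44 and ATF3 of -0.70, and without HAY calf 13 JUND had one of -0.38.

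In the main fit none of the other lists passed camera or had a member past the threshold over the list alone. The median log2 difference was 0.22 for the cell cycle (camera adjusted p = 0.368), 0.12 for cholesterol and sterol synthesis (camera adjusted p = 0.254) and 0.10 for fatty acid and lipid metabolism (camera adjusted p = 0.509), whose mean was negative. It was 0.11 for oxidative stress and heat shock (camera adjusted p = 0.252), -0.09 for the unfolded protein response (camera adjusted p = 0.368), 0.04 for glycolysis and hypoxia (camera adjusted p = 0.812) and 0.14 for erythrocytes (camera adjusted p = 0.598). Leaving out a single calf took 3 of these past the threshold. Without CON calf 14 the cell cycle (median 0.72, adjusted p = 0.000417), cholesterol and sterol synthesis (median 0.37, adjusted p = 0.000258) and oxidative stress and heat shock (median 0.15, adjusted p = 0.015) passed. Without HAY calf 10 the first 2 did (medians 0.59 and 0.28, adjusted p = 0.00435 and adjusted p = 0.0151), and without CON calf 11 their medians were -0.08 and -0.003. When each calf was left out, medians ran from 0.053 to 0.19 for fatty acid and lipid metabolism, from -0.14 to 0.037 for the unfolded protein response, from -0.028 to 0.20 for glycolysis and hypoxia and from -0.066 to 0.32 for erythrocytes. With an estimated correlation none of the 3 lists that passed without CON calf 14 did so in the main fit (adjusted p = 0.884, 0.8 and 0.794).

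Arrays of the same group correlated at a mean Pearson r of 0.982 across genes and arrays of different groups at 0.975, a difference of 0.0062 (exact permutation p = 0.0857, one-sided, over 35 splits). Genes are not independent replicates. The first principal component held 44.6% of the variance, with CON calf 8 at -54.0 and HAY calf 13 at 59.7 at its ends.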

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

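Of the tests in this part, those on the spots around B4GALNT2, on its neighbouring genes, on B4GALNT2 with the stromal covariate, and on the splits for gene lists were planned before their result was seen. All others were chosen after it was seen. Groups of 3 were not examined for outlying calves. In the CON group 6 of 109 measures had a calf set apart, where chance gives 5.45. CON calf 14 stood at 0.43 for DSB, against 0.95 to 1.03 in the other CON calves, and at 0.40 for the score of the unfolded protein response, against -0.08 to 0. CON calf 11 stood apart at -1.25 for SOSTDC1 and 2.88 for CLDN1. CON calf 8 stood at -6.87 for MARVELD3, and CON calf 12 had a median processed signal of 182.25 against 221.55 to 229.4 in the other CON calves.

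Chance could not be excluded for any of the 3 counts. For the 1 gene past the threshold, 6 of the 35 splits of the 7 calves gave as many, with up to 4 in another split. For the 590 genes at least 2-fold apart, 3 of 35 splits gave as many, with up to 777 in another. For the 8 gene lists, 14 of 35 splits gave as many, with up to 14 in another. Genes past the threshold when adjusted over a list alone were not counted over the splits, and that adjustment leaves out the other lists. Chance is thus not excluded for them either. The splits with 777 and 713 genes set apart calves 10, 13 and 14 and calves 8, 11 and 12, which hold the lowest and the highest stromal scores, and so point to a structure of the samples.

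Smooth muscle, fibroblast and endothelial genes were lower in HAY. A lower share of epithelium in CON that brings in every other cell type alike would lower the nerve and glia genes in HAY. Their mean log2 difference was 0.38 (SE 0.09, 8 genes, each well above background on all 7 arrays). This SE is over genes, not calves. Their score ran against the stromal score, from -0.39 in CON calf 8 (stromal score 1.54) to 0.28 in HAY calf 13 (stromal score -1.31). The nerve and glia list therefore cannot decide this, since whether its genes mark nerve or part of the epithelium here was not tested. The median of this list stayed between 0.11 and 0.43 in all 19 alternatives, though the list passed camera in only 6 of them. A candidate explanation is that some samples held more underlying tissue than others whatever the diet: the scores of the 3 lists, centred within groups, correlated at a mean of 0.879. Whether the feeding groups differ in stromal content as well, with an exact permutation p of 0.114, and an effect of forage on these tissues stay open.

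MHC class II and myeloid genes were lower in HAY. A general scaling difference between the arrays is argued against by the mean of the 2 scores, which differed by -0.81 (SE 0.23) between groups and by -0.78 (SE 0.21, 95% interval -1.33 to -0.23) after quantile normalization. This mean differed by -0.46 (SE 0.27) with the stromal score as a covariate, with a 95% interval from -1.21 to 0.28, so stromal content and feeding group cannot be told apart as its source. Slide position cannot be told apart from group either, since only 1 of 10 control probes for added RNA was well above background on all 7 arrays. Fewer of these cells, or less expression per cell, under forage remains an untested possibility.

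B4GALNT2 was 28.1-fold lower in HAY. A local spot artefact is argued against by the 24 surrounding spots, with a median log2 difference of 0.069 (SD 1.02). A change over the whole region is argued against by the 15 tested genes within 500 kb, with a median of 0.00041 (SD 0.46). These ran from -1.51 (SE 0.51) for HOXB8 and -0.73 (SE 0.29) for ABI3 to 0.23 (SE 0.16) for HOXB9. A median cannot exclude a change shared with only a few neighbours. Stromal content is argued against by a log2 difference of -4.93 with the stromal score as a covariate (adjusted p = 0.0317). An inherited variant that sets its level or lies under the probe, and that fell by chance into 1 group, was not tested, and slide row and diet remain open too. Typing the calves, or measuring the transcript with a second probe in more animals, may separate these.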

How the results depend on the processing

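The stromal covariate, an estimated correlation with it or with the slide column, leaving out calves 8 and 13 together, and leaving out calves from the array correlations were chosen after the data were seen. B4GALNT2 passed in 18 of 18 alternatives, with log2 differences from -4.93 to -3.12 and adjusted p from 0.000411 to 0.0317. Slide or scan as a block could not be run with 1 slide and 1 scan. No paired analysis was possible because the groups share no calf numbers. Signal over background limits the 48 genes not well above background on any HAY array and the 25 on any CON array. Except where stated, the cause of a change was not tested.

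The number of genes past the threshold was 1, and 4 (2 higher, 2 lower in HAY) with quantile normalization, 2 with the slide column as a block, 5 without calves 8 and 13, and 1 to 21 when each calf was left out. The 2-fold count was 590, and 250 with normexp, whose offset shrinks differences of dim probes, 337 with the stromal covariate, 310 without calves 8 and 13, and 342 to 950 when each calf was left out. The number of lists passing camera was 8, and 5 with the stromal covariate, 12 with the slide column as a block, 6 to 11 when each calf was left out, 0 with an estimated correlation, alone or with either of these 2 terms, and 0 with fry. The within minus between group correlation was 0.0062, and 0.0022 to 0.0095 when each calf was left out.

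Among the 80 named genes and 27 lists, camera's direction for a list or the sign of a gene turned in the cases below. None of these passed the threshold under the alternative, and only fibroblasts and endothelium had passed it before. Values are log2 differences of genes and median log2 differences of lists, and a median can keep its sign where camera's direction turned. With normexp background correction, the value was -0.088 for ONECUT2, -0.091 for erythrocytes. With quantile normalization, the value was -0.013 for IGFBP5, 0.17 for insulin-like growth factor and growth factor axis, -0.0015 for glycolysis and hypoxia. With stromal score as covariate, and for lists with either correlation, the value was -0.18 for IGFBP5, 0.028 for acid and short-chain fatty acid transport, -0.10 for urea, ammonia, water and sugar transport, 0.0074 for basal keratinocytes, -0.20 for cell cycle, -0.077 for cholesterol and sterol synthesis, -0.050 for fatty acid and lipid metabolism, -0.049 for oxidative stress and heat shock, -0.25 for glycolysis and hypoxia, 0.15 for fibroblasts and matrix, 0.070 for endothelium, -0.092 for erythrocytes. With no filter on dim probes, the value was 0.049 for acid and short-chain fatty acid transport, 0.044 for insulin-like growth factor and growth factor axis, -0.075 for erythrocytes. With slide column as block and either correlation, the value was 0.050 for acid and short-chain fatty acid transport, 0.018 for glycolysis and hypoxia. Without calves 8 and 13, the value was 0.093 for acid and short-chain fatty acid transport, 0.056 for urea, ammonia, water and sugar transport, -0.12 for cell cycle, 0.016 for fatty acid and lipid metabolism, -0.10 for glycolysis and hypoxia, 0.12 for erythrocytes. When each calf was left out in turn, values ran from -0.20 to 0.23 for IGFBP5 (turned without HAY calf 10 or CON calf 11), from -0.18 to 0.021 for KRT5 (turned without HAY calf 13), from 0.050 to 0.17 for acid and short-chain fatty acid transport (turned without CON calf 8), from -0.15 to 0.72 for cell cycle (turned without HAY calf 13 or CON calf 11), from 0.062 to 0.22 for insulin-like growth factor and growth factor axis (turned without HAY calf 9 or HAY calf 10 or CON calf 11 or CON calf 12), from -0.14 to 0.037 for unfolded protein response (turned without CON calf 14), from -0.028 to 0.20 for glycolysis and hypoxia (turned without HAY calf 13 or CON calf 8 or CON calf 11), from -0.066 to 0.32 for erythrocytes (turned without HAY calf 13). Over all alternatives, 1409 values of genes kept direction and side of the threshold and 12 newly passed. Of the values of lists, 395 kept both, 47 no longer passed and 21 newly passed.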

Other observations

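The cell cycle list varied more between calves than between groups: 29 of its 30 members had higher values in HAY, none at an unadjusted limma p under 0.05. Its score was 1.12 in CON calf 14 and 0.88 in HAY calf 13, against -0.996 in CON calf 11. The score of cholesterol and sterol synthesis followed it across the 7 calves (Pearson r = 0.924, exact permutation p = 0.00198, adjusted p = 0.00387, and Spearman rho = 0.857, exact permutation p = 0.0238, adjusted p = 0.0238, over 6 relations computed). Without CON calves 14 and 11 r was 0.806. Calves 13 and 14 also shared column 4 of the slide, and CON calf 14 stood at -49.1 on the second principal component, which held 20.1% of the variance.

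The stromal score followed the first principal component across the 7 calves (Pearson r = -0.980, exact permutation p = 0.000198, the smallest the permutations give here, adjusted p = 0.00119, and Spearman rho = -1, exact permutation p = 0.000397, adjusted p = 0.00238). Without calves 8 and 13 r was -0.955. The component was computed on genes that include those of the score, so part of this relation is built in.

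Of the 17 genes of ketogenesis and butyrate use, 6 had an unadjusted limma p under 0.05, 5 of them higher in HAY. OXCT1, which uses ketone bodies, had a difference of -0.99 (SE 0.32), and none of the 17 passed the adjustment. NQO1, a detoxifying reductase, differed by 1.39 (SE 0.45) and CD14, a receptor of bacterial lipopolysaccharide, by -1.16 (SE 0.30). With the stromal score as a covariate, chosen after the data were seen, 3 lists that had not passed before passed camera with its preset correlation, each lower in HAY: cornified layer and terminal differentiation (median -0.47, adjusted p = 2.18e-05), toll-like receptors and inflammation (median -0.18, adjusted p = 0.000147) and antimicrobial and acute-phase proteins (median -0.29, adjusted p = 0.0134). With an estimated correlation none of them passed in that fit (adjusted p = 0.52, 0.536 and 0.52). OXCT1, NQO1 and CD14 were named after their values were seen.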
